A study of Homo sapiens with 4 samples.

How the data were processed

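Expression was measured in MCF-7, an established line of human breast cancer cells that carries the oestrogen receptor, on 4 arrays of the Affymetrix 3' expression type. According to the labels, 2 arrays came from cells given a control short hairpin RNA (shRNA) and 2 from cells given a pair of shRNA constructs against ATP2C2. Hairpins were delivered by virus and carrying cells were selected with puromycin, per the labels' protocols. The labels call the arrays of a group biological replicates 1 and 2 and give no culture date, scan date or batch, so batches could not be examined. Groups were taken from the sample labels alone.

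The deposited values are 1 log2 expression value per probe set and array, made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes. RMA as a method corrects the background, equalizes the probe distributions between arrays and summarizes the probes of a set on the log2 scale. The same notes name Partek. Its role, both tool versions and any filter are not given in the sources used here. Because RMA equalizes distributions, a change of all transcripts in the same direction would be removed from these values. Its summaries also compress differences near the background, so that folds of dim probe sets are understated. The depth of an array has no count, and the number of arrays limits the precision.

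Each array held 54675 probe sets, of which 62 were control probe sets and were left out. The platform annotation listed 42898 probe sets, 41097 with a single gene symbol and 1801 with several. The other 11777 were not listed and stayed unnamed. Symbols were updated through their Entrez identifiers for 41037 of the 41091 single-gene probe sets tested, and the other 54 kept the annotation's name. For each of the 19775 genes the probe set with the highest mean over the 4 arrays was used, and 10523 genes had more than 1. No genome build is named in the sources used here, so positions are not given. Of 8 genes chosen for report by name, 7 were measured and 1 was not analysed here, as were some members of the gene lists, whose measured numbers are given beside each list.

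Genes were tested with limma 3.58.1 in R 4.3.3, with a linear model of the log2 values and empirical Bayes moderation, two-sided, on the knockdown minus control difference. P-values were adjusted by Benjamini-Hochberg over the 19775 genes, and genes under 0.05 were called. The fit had 2 residual degrees of freedom and a prior of 2.61. A fold change is the antilog of the difference of mean log2 values. Mean values are given with the standard deviation (SD) of the 2 arrays of a group, and log2 fold changes with the moderated standard error (SE).

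Gene lists, 26 in number with 857 members of which 775 were measured, were tested with camera of limma at its preset correlation of 0.01 and adjusted over the lists. Of the members, 22 stood in more than 1 list. ATP2C2 was left out of the Ca2+ list. Genes past the test within a list are also given adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named ATP2C2, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap, up to 4 members of each called list, up to 2 called members of each other list, and the genes chosen by name. Genes named outside the rule are said to be so.

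The alternatives were the replicate number as a block, each array left out in turn, quantile normalization, centring each array on its median, and a filter that kept genes above the 40th percentile of mean expression. Further alternatives took the mean of a gene's probe sets, its most variable probe set or every probe set on its own, an intensity trend or a robust prior (statmod 1.5.0), an adjusted p under 0.10, a change of at least 1.5-fold, and limma's treat against 1.2-fold. Gene lists were also tested with a correlation estimated from the data, with fry, and with camera on ranks. With 1 array left out, the lone array of its group was assumed to vary like the other group. Figures were drawn with matplotlib 3.10.9.

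The code was tested on simulated data in 20 runs of 19775 genes with 2 arrays per group. The test found 71.9% of the 100 genes changed 2-fold and 95.7% of the 100 changed 4-fold, with a false share of 4.45%, and the mean log2 estimates were 1.00 and 1.99. None of 520 unchanged lists was called (0 with camera). The simulated genes varied independently, so these runs could not show false calls that come from correlation between genes. Their variances were drawn from the prior of the fit itself, without regard to intensity. The false share thus holds only under the assumptions of the model and is not the error rate of the real calls. The correlation estimated from the data was 0.562 for the hypoxia list, 0.195 for the mitosis list, 0.123 for the p53 list and 0.0692 for the interferon list. A list of the size of the p53 list shifted by 0.35 was called in 20 of 20 runs with the preset correlation. With an estimated correlation it was called in 0 of 20. The estimated version thus had little power for a shift of this size with 4 arrays, and larger shifts were not simulated. The genes in these runs were independent, so correlation between genes was not what kept the list from being called.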

Results

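The data were 4 arrays of MCF-7 breast cancer cells, 2 from cells with control shRNA and 2 from cells in which ATP2C2 was knocked down with a pair of shRNA constructs. ATP2C2 encodes SPCA2, a Ca2+ pump of the secretory pathway that also promotes Ca2+ entry at the plasma membrane independently of Ca2+ stores. The comparison addressed how loss of this pump alters the transcriptome, and the series title sets it in the context of the DNA damage response. Array medians were 3.83 and 3.86 log2 units in the controls and 3.83 and 3.81 in the knockdowns. The replicate arrays correlated across probe sets at r = 0.996 in the controls and 0.996 in the knockdowns, and arrays of different groups at 0.992 to 0.993. These correlations run across probe sets, which are not independent replicates.

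The targeted transcript was lower on both knockdown arrays. ATP2C2, in its brightest probe set, stood at 6.52 and 6.37 on the control arrays and at 4.80 and 4.70 on the knockdown arrays. The group means were 6.45 ± 0.11 and 4.75 ± 0.07 (log2, SD, n = 2 each). ATP2C2 thus fell by 1.70 on the log2 scale (SE 0.09), to a level 3.25-fold lower (limma, adjusted p = 0.0144). Another probe set of the gene differed by -0.95 without passing when all probe sets were tested (adjusted p = 0.0538), and the last, which was dim (mean 2.71), differed by -0.15. The related Golgi pump gene ATP2C1 did not pass (0.12, SE 0.08, adjusted p = 0.430), and 1 of its 4 probe sets had the opposite sign (-0.36).

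**Figure D1:**
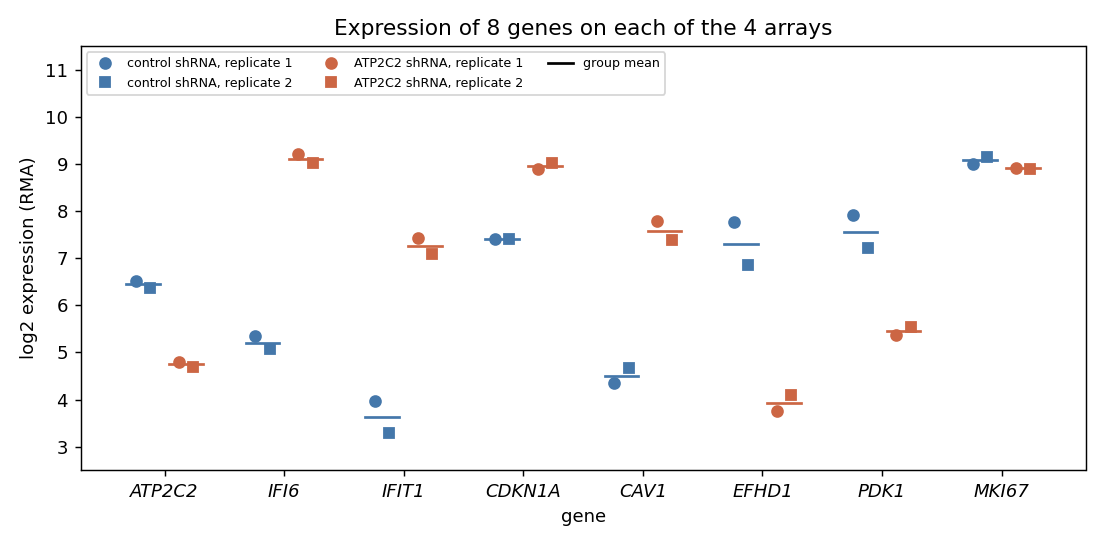
Log2 RMA expression (vertical axis) of 8 genes (horizontal axis) on the 2 control arrays (blue) and the 2 knockdown arrays (orange), with circles for replicate 1, squares for replicate 2 and lines for group means. ATP2C2, EFHD1 and PDK1 were lower on both knockdown arrays, IFI6, IFIT1, CDKN1A and CAV1 were higher, and MKI67 differed by -0.17 without passing the test.

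Knockdown cells had more transcripts of interferon-stimulated genes, p53 target genes and the caveolin genes CAV1 and CAV2, and fewer transcripts of hypoxia-inducible genes. Single genes passed in 22 of 44, 8 of 37 and 4 of 29 measured members of the interferon, p53 and hypoxia lists. Camera's calls of these lists were lost with an estimated correlation (adjusted p = 0.604, 0.884 and 0.884). That version had little power in simulation for a shift of 0.35. In all, 385 of 19775 genes passed the test, 230 higher and 155 lower, or 59.7% higher. Among them 99 were at least 2-fold higher and 46 at least 2-fold lower. All 385 had both knockdown arrays beyond both control arrays, as had 52.6% of all genes, where chance gives 33.3%. The median gene differed by -0.01.

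Of the 10 largest rises, 5 were in members of the interferon list, IFI6, IFIT1, IFIT3, IFI27 and OAS1. Among the others, CAV1, which encodes the coat protein of caveolae, rose 8.43-fold (log2 3.08, SE 0.18, adjusted p = 0.0150). The protocadherin gene PCDH7 rose 8.40-fold (adjusted p = 0.0144) and the peptidase inhibitor gene PI15 7.29-fold (adjusted p = 0.0186), although another PI15 probe set differed by 0.44 on the log2 scale. KCNJ8, a pore subunit of ATP-sensitive K+ channels, rose 6.25-fold (adjusted p = 0.0188), and the sialyltransferase gene ST6GALNAC5 rose 5.64-fold (adjusted p = 0.0115).

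The largest fall was in EFHD1, a mitochondrial Ca2+-binding protein, which was 10.4-fold lower (log2 -3.38, SE 0.33, adjusted p = 0.0337). TMEM45A was 7.52-fold lower (adjusted p = 0.0346). PDK1, the kinase that restrains pyruvate dehydrogenase, was 4.32-fold lower (adjusted p = 0.0435) and the glycolytic aldolase ALDOC 3.70-fold lower (adjusted p = 0.0358). The mitochondrial adenylate kinase AK4 went from 9.13 ± 0.24 to 7.14 ± 0.11 (SD, n = 2 each, adjusted p = 0.0214). The Ca2+-activated K+ channel KCNN4 fell by 1.92 on the log2 scale (adjusted p = 0.0327), and the membrane protein CD109 fell by 1.73 (adjusted p = 0.0150). SPAG4 (log2 -1.68, adjusted p = 0.0492) and NELL2 (log2 -1.67, adjusted p = 0.0481) completed the 10 largest falls together with ATP2C2. In each of these 10 genes control replicate 1 stood above control replicate 2. The control values were 7.77 and 6.84 for EFHD1, 7.34 and 6.49 for TMEM45A, and 7.91 and 7.21 for PDK1.

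With any 1 array left out, all calls were lost. These fits have fewer residual degrees of freedom by construction, so the loss does not tell strong changes from weak ones. The signs of the 385 called genes could not reverse in these fits, because both knockdown arrays of each gene lay beyond both control arrays. The split was 331 higher and 337 lower (49.6% higher) after quantile normalization and 175 and 73 (70.6%) over all probe sets, and the counts reached 923 and 789 without dim genes and 1327 and 979 with an intensity trend.

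Sizes depended on the probe set. Of 24 called genes named here with other probe sets above the 40th percentile of mean expression (3.60), 16 differed over 1.5 times less in at least 1 of them. The smallest log2 differences were -1.07 for AK4, -1.18 for PDK1, -0.38 for CD109, 1.23 for ST6GALNAC5, 0.49 for ZMAT3, -0.57 for MDC1 and 0.60 for CALCR. They were 0.59 for AGR2, 0.003 for ATF5 and -0.03 for SPDEF. With the mean of probe sets the calls of AGR2 (1.04, adjusted p = 0.0530) and ACTA2 (0.37, adjusted p = 0.0645) were lost, and with the most variable probe set those of SPDEF (adjusted p = 0.0604), LDHA (adjusted p = 0.0607) and SDHD (adjusted p = 0.0530). PDK1, P4HA1, LDHA, SPAG4, NELL2 and SDHD lost their calls over all probe sets (adjusted p = 0.0562 to 0.0634) and with a robust prior (adjusted p = 0.0502 to 0.0562), and SPDEF (0.0562) and ATF5 (0.0536) over all probe sets. The mean control value was under 3.60 for PCDH7 (3.50), IFIT3 (2.96), IFI27 (3.55), OAS1 (3.52) and SAMD9 (3.16), and the mean knockdown value for CD109 (3.35), so their folds were set against dim signal and are approximate. The mean control values of IFIT1 (3.63, arrays 3.97 and 3.29) and ST6GALNAC5 (3.61) lay barely above 3.60, so their folds are approximate as well.

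Interferon-stimulated genes were higher as a list, though not every member passed. Of 44 measured members of the list of interferon and viral RNA response, 22 rose and 0 fell, and adjusted over the list alone 33 rose and 0 fell. The median was 0.75 on the log2 scale, and 41 members had positive differences. IFI6, an interferon-induced mitochondrial protein, went from 5.21 ± 0.19 to 9.11 ± 0.14 (SD, n = 2 each), 15.0-fold higher (log2 3.90, SE 0.13, adjusted p = 0.00990). The RNA-binding antiviral proteins IFIT1 and IFIT3 rose 12.4-fold (adjusted p = 0.0215) and 7.88-fold (adjusted p = 0.00990), and IFIT5 rose 4.27-fold (adjusted p = 0.00990). Another IFIT3 probe set differed by 0.99 on the log2 scale. SAMD9, an antiviral factor, rose 4.56-fold (adjusted p = 0.00990), IFI27 7.47-fold (adjusted p = 0.0144) and OAS1, a sensor of double-stranded RNA, 5.19-fold (adjusted p = 0.0140). Camera called the list higher (adjusted p = 1.97e-25), a call that was lost at adjusted p = 0.604 with an estimated correlation. Of 25 measured NF-kB and inflammatory cytokine genes, 0 passed, also adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.769).

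Transcripts of p53 target genes were also higher. Of 37 measured members, 8 rose and 0 fell, and adjusted over the list alone 20 rose and 4 fell. The median was 0.35, with 30 members positive and 7 negative. CDKN1A, the cyclin-dependent kinase inhibitor p21, went from 7.40 ± 0.01 to 8.96 ± 0.09 (SD, n = 2 each), 2.94-fold higher (log2 1.56, SE 0.08, adjusted p = 0.0144). PLK2, a polo-like kinase, rose 2.68-fold (adjusted p = 0.0322), TIGAR, a regulator of glycolysis, 1.97-fold (adjusted p = 0.0285) and the RNA-binding protein ZMAT3 1.87-fold (adjusted p = 0.0265). Camera called the list higher (adjusted p = 6.87e-07), a call that was lost at adjusted p = 0.884 with an estimated correlation.

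Hypoxia-inducible genes, targets of the HIF transcription factors, were lower. Of 29 measured members, 4 fell and 0 rose, and adjusted over the list alone 24 fell and 1 rose. The median was -0.76, and 27 members had negative differences. Besides PDK1, which was 4.32-fold lower, the mitophagy receptor BNIP3 was 2.88-fold lower (log2 -1.53, adjusted p = 0.0315). P4HA1, a collagen prolyl hydroxylase subunit, was 2.65-fold lower (log2 -1.40, adjusted p = 0.0435) and the lactate dehydrogenase gene LDHA 1.67-fold lower (log2 -0.74, adjusted p = 0.0444). Camera called the list lower (adjusted p = 2.13e-12), a call that was lost at adjusted p = 0.884 with an estimated correlation. The calls of PDK1, P4HA1 and LDHA were lost over all probe sets and with a robust prior. The control arrays also differed from each other in this list. Relative to the control mean, its median was 0.19 and -0.19 on the control arrays and -0.79 and -0.76 on the knockdown arrays.

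Mitotic genes were slightly lower as a list, with no single gene called. Of 50 measured genes of G2/M and mitosis, 0 rose and 0 fell, also adjusted over the list alone, and 35 had negative differences, with a median of -0.11. The members with the smallest adjusted p were ASPM (-0.42, adjusted p = 0.106), KIF2C (-0.26, 0.139), PRC1 (-0.25, 0.139) and HMMR (-0.33, 0.149). Camera called the list lower (adjusted p = 0.0127), a call that was lost at adjusted p = 0.884 with an estimated correlation, and also at adjusted p = 0.0745 without control replicate 2 and adjusted p = 0.437 without knockdown replicate 1, when the median was -0.06. The proliferation marker MKI67 differed by -0.17 (SE 0.09, adjusted p = 0.321) and did not pass. The list of G1/S and DNA replication had 46 measured members, of which 0 passed, also adjusted over the list alone, and was not called (median -0.06, adjusted p = 0.330). Neither were the replication-dependent histones, of which 0 of 25 passed and adjusted over the list alone 1 rose and 1 fell (median -0.08, adjusted p = 0.330). Probe sets of these near-identical histone genes can share signal.

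**Figure D2:**
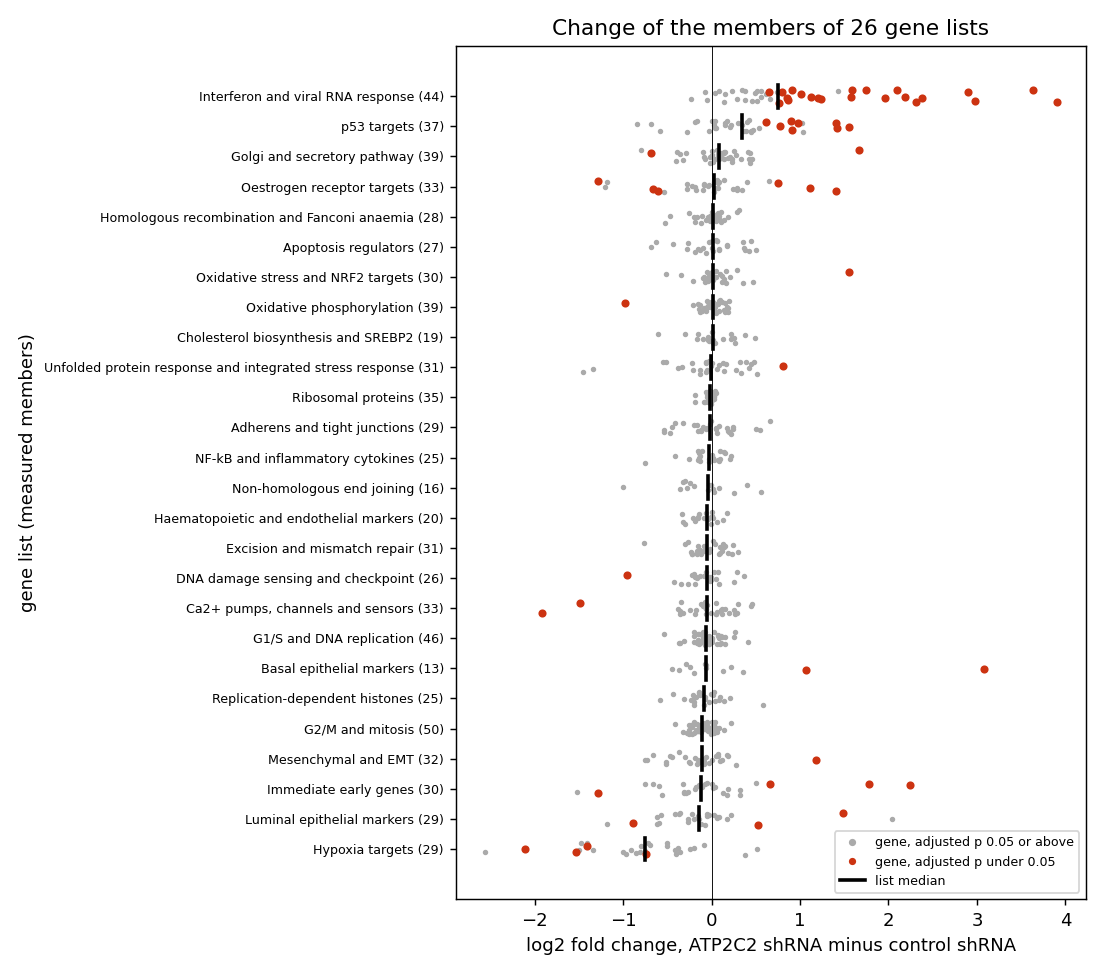
Log2 fold change, knockdown minus control, of the measured members of 26 gene lists, with 1 point per gene, red where its adjusted p was under 0.05, and a black bar at each list's median. The medians of the interferon list (0.75) and the p53 list (0.35) were the highest, and that of the hypoxia list (-0.76) was the lowest.

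Genes that sense and repair DNA damage were not called as lists. Of 26 measured genes of damage sensing and checkpoints, 1 fell and 0 rose, and adjusted over the list alone 3 fell and 1 rose (median -0.06, camera adjusted p = 0.330). The gene that fell was MDC1, the scaffold that binds phosphorylated H2AX at DNA breaks, which went from 8.56 ± 0.10 to 7.61 ± 0.09 (SD, n = 2 each), 1.93-fold lower (log2 -0.95, SE 0.09, adjusted p = 0.0337). ATM, the kinase that signals double-strand breaks, did not pass (0.08, SE 0.10, adjusted p = 0.706), and its bright probe sets differed in sign (-0.15 to 0.22). Of 28 measured genes of homologous recombination and the Fanconi anaemia pathway, 0 passed, and adjusted over the list alone 2 fell (median 0.02, camera adjusted p = 0.942). Of 16 genes of non-homologous end joining, 0 passed, and adjusted over the list alone 2 rose and 5 fell (median -0.04, adjusted p = 0.601). Of 31 genes of excision and mismatch repair, 0 passed, and adjusted over the list alone 1 fell (median -0.05, adjusted p = 0.665).

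Among 33 measured Ca2+ pumps, channels and sensors other than ATP2C2, 2 fell and 0 rose, with the same numbers adjusted over the list alone, and the list was not called (median -0.06, adjusted p = 0.769). They were KCNN4, given above, and CACNA1D, a subunit of L-type Ca2+ channels, which was 2.79-fold lower (log2 -1.48, adjusted p = 0.0289). Other probe sets of CACNA1D differed by -0.30 and -0.60, and with the mean of its probe sets the call was lost (-0.58, adjusted p = 0.0834). The store-operated channel gene ORAI1 (0.25, SE 0.07, adjusted p = 0.145) and the Ca2+ sensor gene of the endoplasmic reticulum STIM1 (-0.09, SE 0.11, adjusted p = 0.687) did not pass. Of 39 genes of the Golgi and secretory pathway, 1 rose and 1 fell, and adjusted over the list alone 7 rose and 3 fell (median 0.08, adjusted p = 0.125). The mannosidase gene MAN1A1 rose 3.18-fold (adjusted p = 0.0150) and the glycosyltransferase gene MGAT4A was 1.61-fold lower (log2 -0.69, adjusted p = 0.0371), both enzymes that process N-glycans. The call of MGAT4A was lost with the mean of its probe sets (-0.19, adjusted p = 0.341), with the most variable probe set (adjusted p = 0.0602) and over all probe sets (adjusted p = 0.0562).

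The oestrogen receptor gene ESR1 did not pass (-0.08, SE 0.09, adjusted p = 0.672). Its 33 measured target genes went both ways, with 3 risen and 3 fallen, and adjusted over the list alone 3 and 6 (median 0.03, adjusted p = 0.977). The calcitonin receptor gene CALCR rose 2.16-fold (adjusted p = 0.0214), and EGR3, a zinc finger transcription factor, was 2.44-fold lower (log2 -1.29, adjusted p = 0.0285). Of 29 luminal epithelial markers, 2 rose and 1 fell, and adjusted over the list alone 3 rose and 8 fell (median -0.14, adjusted p = 0.114). AGR2, a protein disulfide isomerase, rose 2.79-fold (adjusted p = 0.0339), and the transcription factor gene SPDEF was 1.85-fold lower (log2 -0.89, adjusted p = 0.0402). Of 13 basal epithelial markers, 2 rose, and adjusted over the list alone 3 rose and 2 fell (median -0.07, adjusted p = 0.769). The pair was CAV1, 8.43-fold higher, and CAV2, 2.10-fold higher (adjusted p = 0.0328), although 1 dimmer probe set of CAV2 (mean 3.79) differed by -0.11. Of 32 mesenchymal markers 1 rose, ACTA2, smooth muscle actin (2.27-fold, adjusted p = 0.0205), and adjusted over the list alone 1 rose and 1 fell (median -0.11, adjusted p = 0.330). Of 20 haematopoietic and endothelial markers, 0 passed, also adjusted over the list alone (median -0.05, adjusted p = 0.378).

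Immediate early genes, which respond to growth factors and Ca2+ signals, also went both ways, with 3 of 30 risen and 1 fallen, and adjusted over the list alone 3 and 5 (median -0.12, adjusted p = 0.600). The nuclear receptor gene NR4A2 rose 4.73-fold (adjusted p = 0.0150), and the gene that fell was EGR3, 2.44-fold lower. In the list of the unfolded protein and integrated stress responses, 1 of 31 rose, ATF5 (1.74-fold, adjusted p = 0.0358), and adjusted over the list alone 8 rose and 5 fell (median -0.006, adjusted p = 0.665). In that of oxidative stress and NRF2 targets, 1 of 30 rose, also adjusted over the list alone, the aldo-keto reductase gene AKR1C3 (2.93-fold, adjusted p = 0.0186; median 0.02, adjusted p = 0.600). In that of oxidative phosphorylation, 1 of 39 fell, also adjusted over the list alone, the complex II subunit gene SDHD (log2 -0.98, 1.97-fold lower, adjusted p = 0.0470; median 0.01, adjusted p = 0.816). No gene passed over all genes in the other lists. Adjusted over the list alone, 2 cholesterol biosynthesis genes rose and 1 fell of 19 (median 0.01, adjusted p = 0.640), and 5 apoptosis regulators rose and 2 fell of 27 (median 0.02, adjusted p = 0.665). Of 29 junction genes 2 rose and 4 fell adjusted over the list alone (median -0.02, adjusted p = 0.816), and of 35 ribosomal protein genes 0 passed (median -0.02, adjusted p = 0.665).

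Camera called 4 of the 26 lists, 2 higher and 2 lower, of which 0 were called with an estimated correlation. The smallest unadjusted p of that version was 0.0232, for the interferon list. It also missed a shifted list of independent simulated genes. A lost call therefore does not show that correlation between genes had made it, nor does it exclude this. Fry, which asks only whether a list's genes move 1 way on balance, called 2, the interferon list (adjusted p = 0.0311) and cholesterol biosynthesis (adjusted p = 0.0391). Median, mean and test differed in sign in 5 uncalled lists, those of homologous recombination, oestrogen receptor targets, basal markers, the unfolded protein response and oxidative phosphorylation. The log2 ratio of 3' to 5' control probe sets, a sign of RNA integrity, was -0.01, 0.009, -0.03 and -0.04 for GAPDH on the control and knockdown arrays in order, and 0.21, 0.12, 0.20 and 0.24 for ACTB.

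**Figure D3:**
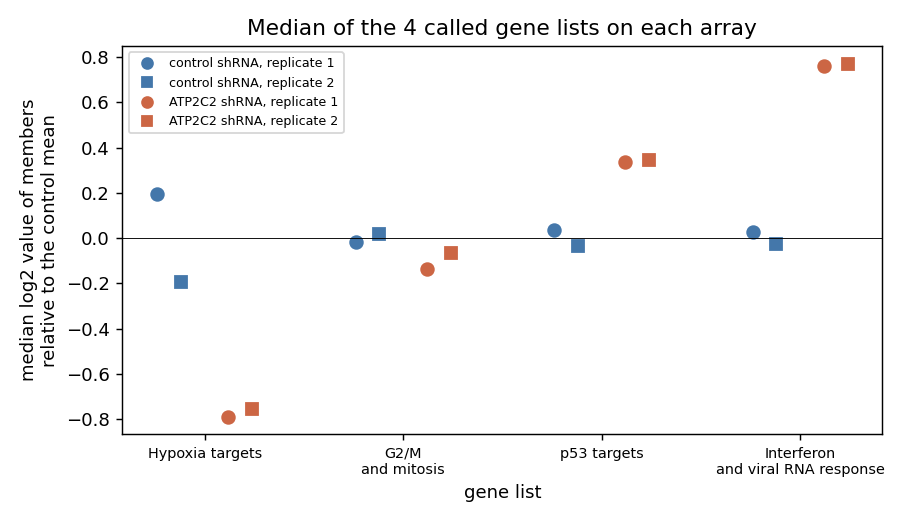
Median over the members of each of the 4 called gene lists (horizontal axis) of the log2 value relative to the control mean (vertical axis), with 1 point per array, controls in blue and knockdowns in orange. The interferon list stood at 0.76 and 0.77 and the p53 list at 0.34 and 0.35 on the knockdown arrays, and the hypoxia list stood at 0.19 and -0.19 on the control arrays.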

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

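Of the tests in this part, those on markers of other cells, on unnamed probe sets, on vector and hairpin responses, on differences between the control arrays and on p53 targets that interferon also induces were chosen only after the changes in the gene lists were seen. So was the reading of the hypoxia list against each control as a test, while leaving out each array was planned. The outcome of the 1 on p53 targets that interferon also induces was not known when it was chosen. Outside the genes compared above, 13522 probe sets had no single named gene, and 5 of them passed the test when adjusted among themselves, 4 higher and 1 lower in the knockdown (1504 at an unadjusted p under 0.05). The largest rise was 2.71 on the log2 scale (adjusted p = 0.0114), and the fall was -3.23 (adjusted p = 0.0170).

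The rise of interferon genes had a median of 0.751 on the log2 scale. Blood, endothelial or mesenchymal cells in the knockdown cultures would have brought their own transcripts. The 52 markers of such cells had a median of -0.0947, with 1 risen (ACTA2) and 0 fallen. The 5 most abundant lay between -0.66 (MMP9) and 0.28 (COL1A1). A pooled median could hide a single cell type. The largest rise among the 20 blood and endothelial markers was 0.18, which argues against those cells. Of the 32 mesenchymal markers 22 were negative and 10 positive, with a median of -0.11. This argues against mesenchymal cells less firmly, because ACTA2 rose. The markers did not include CAV1 and CAV2, which also rose. The controls also carried an shRNA, so a response common to any hairpin vector would be shared by both groups. A response particular to these hairpins or to an unequal amount of virus, which the labels do not give, may still raise these genes and cannot be told apart from an effect of losing ATP2C2, because 1 mixture of hairpins was used, without re-expression. The biological explanation, loss of the pump, therefore stays open and untested.

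The fall of hypoxia genes had a median of -0.76. It did not rest on control replicate 1, since against control replicate 2 alone the median was -0.591 with 27 of 29 members lower, and against control replicate 1 alone it was -0.947 with 28 of 29 lower. An oxygen or medium state that differs from culture to culture stays open as a candidate explanation. The same list differed by 0.39 between the control arrays, with 26 of 29 members higher in replicate 1. This was farther from 0 than 100% of 10000 random lists matched on mean expression, whereas the knockdown arrays differed by -0.02 (percentile 49.9). The random lists were not matched on correlation between genes, which was estimated at 0.562 for the hypoxia list. The percentile therefore does not tell how unusual such a difference is for co-regulated genes. An effect of losing ATP2C2 stays open as well.

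The rise of p53 targets had a median of 0.348. Without the 4 members that interferon also induces, TRIM22, FAS, PMAIP1 and TNFRSF10B, the remaining 33 had a median of 0.295 with 27 positive and 7 risen. The shift was thus also present in the other members. Taking 4 of 37 members out can move a median by only a few ranks, so this outcome was nearly fixed in advance. It does not address an effect of interferon on the members that were kept. The list also differed by 0.07 between the control arrays (24 of 37 higher in replicate 1, percentile 98.9 of matched random lists), against 0.348 between the groups. The limit on the percentile given for the hypoxia list holds here too, and a culture state that differs from culture to culture stays open. A response particular to these hairpins or to an unequal amount of virus could also raise p53 targets and cannot be told apart from loss of ATP2C2, for the same reason as for the interferon genes.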

How the results depend on the processing

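The unadjusted threshold, the other ATP2C2 probe sets and the shortened p53 list were tried only after the data were seen. Of the genes higher (230) and lower (155), counts were 0 and 0 with the replicate number as a block and 0 to 0 in both directions with each array left out in turn. These fits have fewer residual degrees of freedom by construction. Unadjusted p under 0.05 was met by 1697 and 1839 genes with the block (smallest adjusted p 0.152), 1326 to 1593 and 1471 to 1687 without 1 array, and 2180 and 2278 with all 4. All 385 called genes kept their sign in each of these fits. That was fixed in advance, because both knockdown arrays of each gene lay beyond both control arrays. Their unadjusted p under 0.05 with the block is no separate support, since the genes were chosen from the same arrays. The labels do not say whether replicates of the same number were processed together. The correlation of same-numbered deviations was -0.0889, which cannot settle this with 2 arrays per group. The block changed the call of none of the 4 gene lists.

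Other counts that moved over 1.5 times were 354 higher with median centring, 337 lower with quantile normalization, 923 and 789 without dim genes (fewer genes tested), 236 lower with the mean of probe sets, 87 lower with the most variable, 73 lower with all probe sets, 1327 and 979 with an intensity trend, 95 lower with a robust prior, 724 and 675 at adjusted p under 0.10, and 61 and 14 with treat; the last 2 follow from the threshold, and for the rest the cause was not tested. Neither scaling moved the median gene by over 0.1, and under both the 43 called named genes kept their call and the other 10 gained none. ATP2C2 fell by 1.70 with the block (adjusted p = 0.169), and gave -1.78 to -1.63 without 1 array. It gave -0.935 with the mean of its probe sets (adjusted p = 0.0160), and -0.95 and -0.15 in the other probe sets. Gene lists called numbered 0 with an estimated correlation and 2 with fry, against 4. In these fits, signs of named genes reversed only in uncalled ones: without 1 array ATM gave -0.034 to 0.19, ESR1 -0.17 to 0.016 and STIM1 -0.23 to 0.043, and ATP2C1 gave -0.36 with its most variable probe set. Of the 53 named genes, 43 lost their call with the block and with each array left out, 4 with the mean of probe sets, 4 with the most variable, 9 with all probe sets and 6 with a robust prior, while 1 gained a call without dim genes and 5 with an intensity trend. Signal near the background limits dim genes.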

Other observations

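The groups in this part were chosen after the values were seen, and their tests are descriptions of these arrays. Glycolytic enzymes were lower as a group, with negative differences in 16 of 16 genes and a median of -0.49 on the log2 scale. Over all genes 2 fell, ALDOC (-1.89, adjusted p = 0.0358) and LDHA (-0.74, adjusted p = 0.0444), and 12 fell adjusted over the list alone (camera adjusted p = 2.18e-09, adjusted p = 0.158 with an estimated correlation). The hypoxia list holds 5 of the 16, ALDOA, ENO1, HK2, LDHA and PGK1, and the other 11 had a median of -0.32. That list does not hold every hypoxia-inducible gene, so this split does not separate a fall of glycolytic genes from that of hypoxia genes. Control replicate 1 stood above control replicate 2 in 15 of 16, by a median of 0.13, as in the hypoxia list. Metallothioneins, which bind zinc and copper, had 9 of 10 negative differences and a median of -0.42 (camera adjusted p = 1.91e-05, adjusted p = 0.0764 with an estimated correlation). MT2A (-0.96, adjusted p = 0.0232), MT1H (-0.71, adjusted p = 0.0358), MT1X (-0.70, adjusted p = 0.0402) and MT1HL1 (-0.55, adjusted p = 0.0462) fell, and the other 6 did not pass. These genes are near-identical, so that their probe sets can share signal.

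Genes of antigen presentation on MHC class I had 14 of 15 positive differences and a median of 0.34 (camera adjusted p = 3.69e-08, adjusted p = 0.0764 with an estimated correlation). The immunoproteasome subunits PSMB9 (1.75, adjusted p = 0.0239) and PSMB10 (0.70, adjusted p = 0.0481) and the trimming peptidase ERAP1 (0.93, adjusted p = 0.0232) rose, and 12 of the 15 did not pass. The negative gene was the immunoproteasome subunit PSMB8 (-0.23). PSMB8, ERAP2 and NLRC5 were dim, with means under 3.60 in both groups. HLA-B, HLA-C, HLA-E and HLA-F are similar in sequence, so their probe sets can share signal. The interferon list holds 3 of the 15, PSMB8, PSMB9 and TAP1, and the other 12 were all positive, with a median of 0.31. That list does not hold every interferon-induced gene, so this rise is not separate from that of the interferon genes. All 4 genes of the ID family, inhibitors of basic helix-loop-helix transcription factors, rose, ID4 by 2.33, ID1 by 1.24, ID3 by 1.04 and ID2 by 0.89 on the log2 scale.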
